A study of Homo sapiens with 3 samples.

How the data were processed

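RNA from 3 human cultures was measured on 1 Affymetrix expression array each. The cultures were untreated MRC5 lung fibroblasts, MRC5 treated with interferon gamma (IFN gamma) at 200 IU/ml for 24 hours, and untreated PGF B-lymphoblastoid cells. Total RNA was extracted with a Qiagen RNeasy Plus kit and labelled by the Affymetrix procedure, per the labels' protocols. The values used are the authors' deposited log2 values, 1 per probe set and array. They were made with RMA (robust multi-array average, which corrects background, equalises the distributions of the arrays and summarises the probes of a set), per the submitters' processing notes. The RMA version, the software that ran it and any filter are not given in the sources used here. Scanner files and detection calls were not used here.

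The table held 54675 probe sets. The medians of the deposited log2 values were 5.28 for untreated MRC5, 5.28 for treated MRC5 and 5.26 for PGF. Many values were exactly equal between arrays. On the MRC5 arrays 39.9% of probe sets had the same value in both cultures, and 23.4% had the same value on all 3 arrays. Among the genes that entered each comparison, 21.1% were equal between treated and untreated MRC5 and 12.5% between PGF and untreated MRC5. RMA summarises with medians over probes, which can return equal values for arrays that differ little. Whether this step produced the equal values was not tested. An equal value is therefore not evidence that a transcript level was the same in both cultures.

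Gene names came from the platform annotation supplied with the value table. It gave 1 symbol for 41097 probe sets, several for 1801 and none for 11777. Of the probe sets with 1 symbol, 41043 were matched by Entrez ID to the RefSeq gene table of assembly GRCh38.p14, which was used only for current names and for the order of neighbouring genes. No coordinates are given, because the data name no genome build. Probe sets with several symbols or none were left out of the comparisons between genes. XIST and genes of the Y chromosome were left out. Some members of the fixed gene lists had no named probe set and are not reported here. Counts of list members therefore give how many were measured.

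A gene was represented by the probe set of its symbol with the highest mean over the 3 arrays, which gave 19740 genes. A gene entered a comparison when the higher of its 2 values reached 5.28, the median of all values over the 3 arrays. The difference of the 2 log2 values was then taken. With 1 array per group no spread between cultures can be estimated, so there is no test, no p-value and no error on any difference. A fixed rule of at least 2-fold (1 on the log2 scale) sets which genes are called higher or lower, and the calls describe these arrays. The number of arrays limits the precision. Each design comparison was treated this way: treated against untreated MRC5, PGF against untreated MRC5, and PGF against treated MRC5.

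Before the data were examined, 32 gene lists were fixed. They covered antigen presentation (MHC class II with CIITA, class II transcription factors, MHC class I with NLRC5, antigen processing, standard proteasome beta subunits, the MHC class III region), interferon responses (guanylate-binding proteins, receptor, STAT and IRF genes, chemokines, antiviral genes, IFN gamma effector genes), complement, cell death, NF-kB, p53 targets and the cell cycle. Others covered extracellular matrix, contractile genes, fibroblast, B cell, plasma cell, B lymphoblastoid, T cell, myeloid, epithelial and endothelial markers, cholesterol synthesis, oxidative phosphorylation, stress response, immediate early genes, ribosomal proteins and reference genes. For each list the median difference of all measured members was set against 10000 random lists of the same size, matched on mean level in 20 bins. The percentile of the median describes these arrays and is not a p-value. Symbols of 2 members were updated through the synonym column.

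The rule for named genes was also fixed in advance. It takes the 12 largest rises and the 12 largest falls of treated and of PGF cells against untreated MRC5, up to 4 members per direction of each list described, and the members of the MHC and antigen processing lists. For PGF against treated MRC5 only list members are named. Genes named outside this rule are said to have been chosen after their values were seen.

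Both comparisons against untreated MRC5 share that array. The overlap of their calls was therefore set beside 100 simulations of unchanged arrays, beside the overlap of independent lists (n1 × n2 / N) and beside random gene sets matched on mean level. The alternatives tried were the median of a gene's probe sets, leaving out probe sets with names ending in _x_at or _s_at (which can hybridise with related transcripts), no level filter or one at the 75th percentile (7.17 on the log2 scale), loess scaling with a span of 0.2, centring each array on the median of the reference genes, adding 32 on the linear scale, and thresholds of 1.5-fold and 4-fold. Setting the median difference of the reference genes to 0 was added after the data were seen. The median of a gene's probe sets was taken on each array before the difference. A different probe set can therefore stand for the gene on each array. The result need not be the median of the differences of its probe sets. Values of single genes under the alternatives are given without the level filter, so some rest on dim probe sets.

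The steps were tested on simulated data for treated against untreated MRC5, with 19740 genes and 200 of them changed. All 3-fold, 4-fold and 8-fold changes were recovered (100% at each size), and 0 of the 1.5-fold genes and 0 unchanged genes were called. Of 200 unchanged lists of 25 genes, 2.5% lay in the outer tails of their random lists, which hold 5% by construction. The changed genes and the unchanged lists were drawn only from genes well above the level filter. The simulated noise had an SD of 0.1 on the log2 scale. With it a 3-fold change could hardly miss the threshold, and a 1.5-fold change could hardly reach it. The result therefore checks the code, and says nothing of dim genes or of variation between cultures. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.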

Results

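Gene expression was measured in 2 human cell lines, 1 of them in 2 states. MRC5 is a line of fibroblasts from human fetal lung, and it was grown untreated or with IFN gamma at 200 IU/ml for 24 hours. IFN gamma is the cytokine by which T cells and natural killer cells raise antigen presentation and antimicrobial defence in other cells. PGF is a B-lymphoblastoid line, a B cell line transformed by Epstein-Barr virus, and served as a cell type that presents antigen without treatment. Each group was 1 array, with no replicate, so every difference below is a difference between 2 arrays without an error. The words rose and fell stand for a difference of at least 2-fold. Differences are log2 differences of the authors' RMA values, and fold values are computed from them. Across probe sets, which are not independent replicates, the correlation between arrays was 0.990 for treated with untreated MRC5 and 0.872 for PGF with untreated MRC5. The control probe sets for the 3' and 5' ends of ACTB differed by -0.15, -0.15 and -0.08 (3' minus 5') on the untreated MRC5, treated MRC5 and PGF arrays. Those of GAPDH differed by -0.08, -0.02 and 0.02.

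The first comparison asked which genes responded to IFN gamma in MRC5. The largest rise was that of CXCL11, from 2.86 to 13.02, a log2 difference of 10.16. The related chemokines CXCL10 and CXCL9, which attract activated T cells through the same receptor, rose by 7.84 and 6.74. IDO1, which starts the breakdown of tryptophan, rose by 8.42. The other genes among the 12 largest rises were CMPK2, a mitochondrial nucleotide kinase (6.40), PLAAT4 (5.96), the GTPases GBP5 (5.83), GBP4 (5.83) and GBP2 (5.22), the IL-18 inhibitor IL18BP (5.29), IFI44L (5.11) and OAS2 (4.92), a sensor enzyme for double-stranded RNA. The 3 probe sets of IL18BP differed by 5.29, 0.31 and 0.13, and its rise was 0.73 when the median of their levels was taken on each array. Differences of genes that started near the bottom of the scale rest on a dim untreated value, and with 32 added on the linear scale CXCL11 was at 7.73 and IDO1 at 7.34.

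Of 13127 genes, 243 were at least 2-fold higher on the treated array and 85 at least 2-fold lower, so 74.1% of the calls were rises. Rises of at least 4-fold numbered 96 against 6 falls, and rises of at least 8-fold 52 against 1. Of the 243 raised genes, 89 were on the interferon and antigen presentation lists and 138 on none of the lists. The median difference over all genes was 0.00. Centring on the median level of the reference genes moved it to 0.94, and 99.8% of the calls were then rises. With the median difference of the reference genes set to 0 it stayed at 0.00, and 73.9% were rises.

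**Figure D1:**
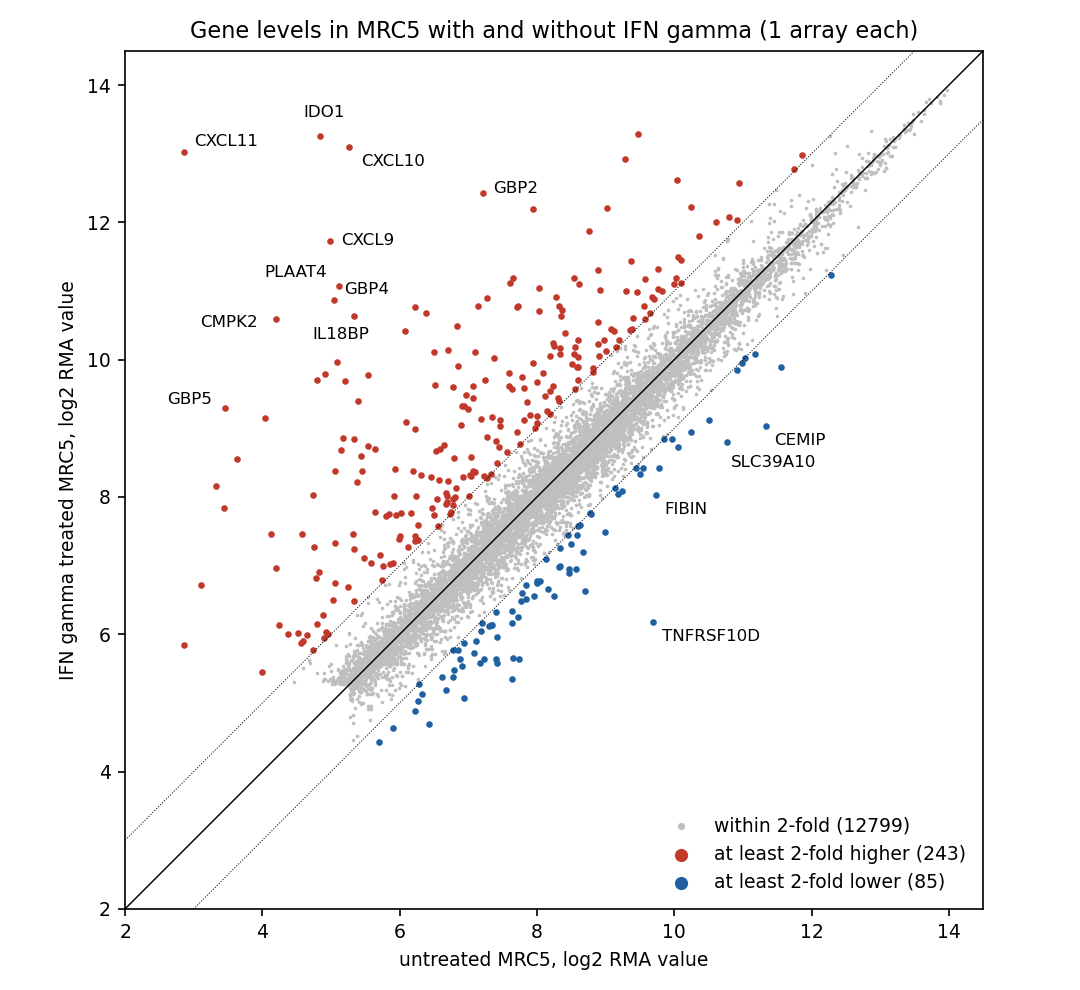
Each point is 1 of the 13127 genes, with its log2 RMA value on the untreated MRC5 array on the x axis and on the IFN gamma treated array on the y axis. The solid line marks equal values and the dotted lines 2-fold; the 243 raised genes (red) reach a difference of 10.16 for CXCL11, and the 85 lowered genes (blue) reach -3.52 for TNFRSF10D.

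The MHC class II genes, which present peptides to CD4 T cells, rose in part. The list had 15 of 17 members measured, and 6 of the 13 that passed the level filter rose. These were CD74, the invariant chain (4.34, 20.2-fold), HLA-DMA (3.51), HLA-DPA1 (3.0), HLA-DRA (2.93), HLA-DMB (2.48) and HLA-DRB1 (1.52). The 3 probe sets of CD74 differed by 4.34, 2.01 and 0.04. With the median of the probe sets CD74 was at 1.43 and HLA-DPA1 at 1.83, and without the _x_at and _s_at ones HLA-DRA was at 4.56. The differences of HLA-DQA1, HLA-DQB1, HLA-DPB1 and HLA-DOB were 0.17, 0.16, 0.30 and 0.14. CIITA, the coactivator that switches class II genes on, differed by 0.60, and by 1.51 on another of its 3 probe sets. HLA-DRB4 differed by 0.78, HLA-DRB6 by 0.57, HLA-DQB2 by -0.05 and HLA-DOA by 0.00, and another HLA-DOA probe set by 0.84. The list median was 0.60, at percentile 100 of the random lists. It was 0.27 without the _x_at and _s_at probe sets. Of the 7 class II transcription factors none rose, the largest difference was 0.92 for RFX5 and the median was -0.04 (0.90 when centred on the median level of the reference genes).

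The class I pathway rose as well. With 9 of 10 members of the class I list measured, 5 rose: NLRC5, the coactivator of class I genes (2.42), MICB (1.63), HLA-E (1.62), HLA-F (1.22) and HLA-B (1.13). The differences of HLA-G, HLA-C, B2M and MICA were 0.90, 0.84, 0.47 and -0.01. Other probe sets of HLA-C differed by 1.04, 1.06 and 1.08, and those of HLA-G by 1.03, 0.78 and 0.69. The 3 probe sets of HLA-E differed by 1.62, 1.62 and 0.88, and it was at 0.88 with the median of their levels. HLA-F was at 0.28 without the _x_at and _s_at probe sets, on a probe set under the level filter on both arrays (4.80 and 5.07). Class I genes are similar in sequence, so a probe set can read more than 1 of them. Of 15 measured antigen processing genes 9 rose and 1 fell, with a median of 1.37 at percentile 100. The protease CTSS rose by 4.48, the immunoproteasome subunits PSMB9, PSMB10 and PSMB8 by 3.50, 2.68 and 2.1, and the peptide transporter subunits TAP1 and TAP2 by 3.19 and 3.07. ERAP1 (1.78), TAPBPL (1.37) and PSME1 (1.17) rose too. CTSS was at 2.85 without the _x_at and _s_at probe sets. The chaperone CALR fell, and its 3 probe sets differed by -1.38, -0.53 and -2.65. It was at -0.54 with the median of its probe sets, which set different probe sets against each other. The 7 standard proteasome beta subunits held no gene past 2-fold, with a median of 0.09. Of the 27 MHC class III region genes that passed the filter 0 rose and 0 fell, and the median was 0.00.

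**Figure D2:**
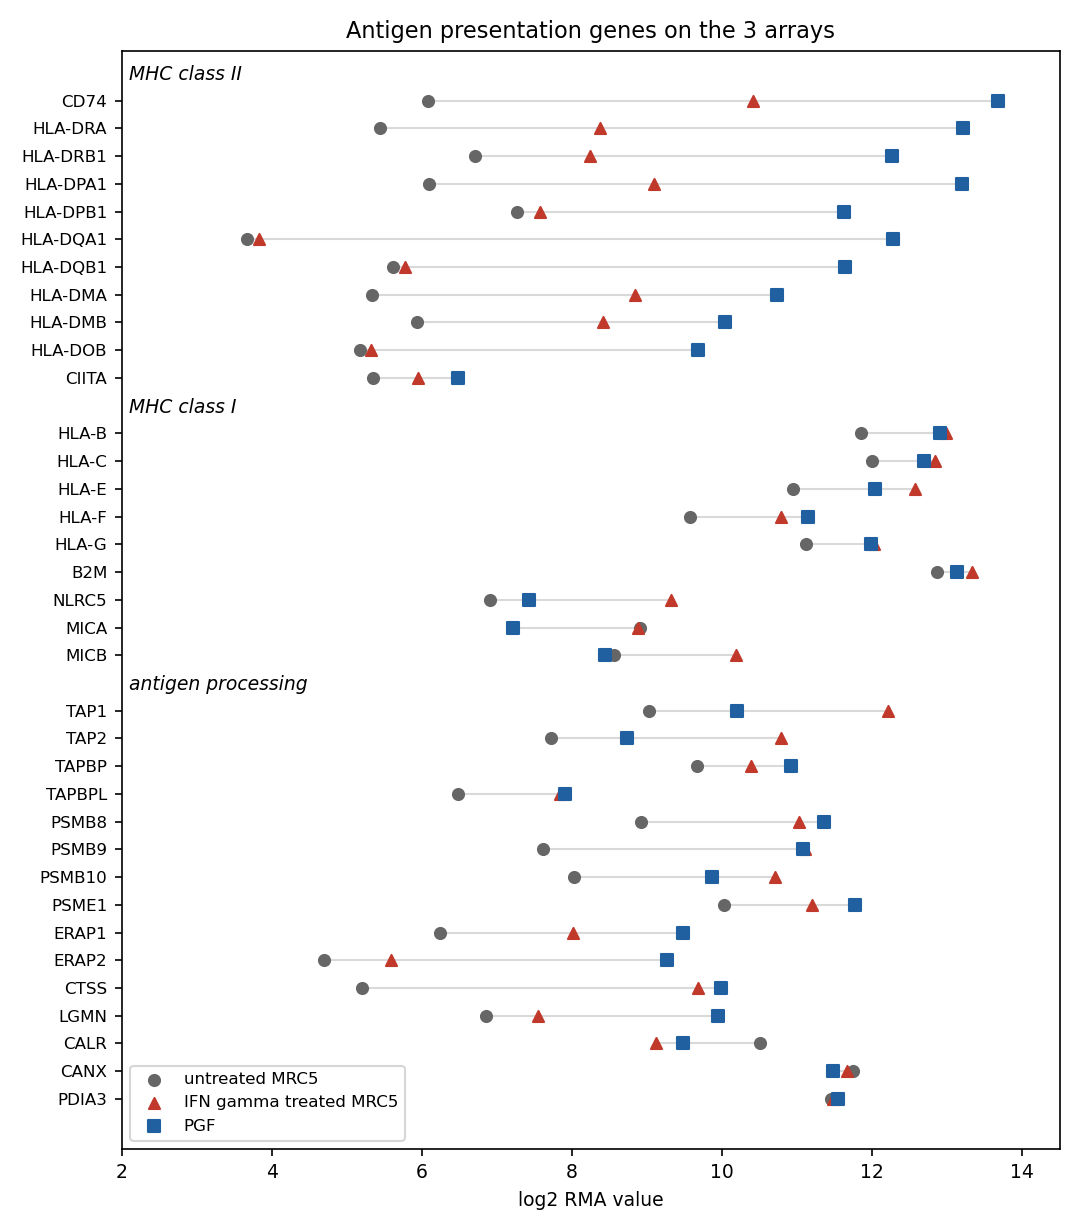
Log2 RMA values (x axis) of 11 class II, 9 class I and 15 antigen processing genes on the arrays of untreated MRC5 (grey circles), IFN gamma treated MRC5 (red triangles) and PGF (blue squares), 1 array each. CD74 stood at 6.08, 10.41 and 13.68, while HLA-DQA1 stood at 3.66, 3.83 and 12.27.

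Interferon response genes outside antigen presentation rose as well. All 5 guanylate-binding protein genes that passed the filter rose, with a list median of 4.52. GBP1 rose by 3.82 and GBP3 by 1.98. Of 39 antiviral genes that passed, 34 rose, led by IFI44L, OAS2, XAF1 (4.89) and the RNA sensor IFIH1 (4.85), and the list median was 2.17. IFIH1 was at 2.70 with the median of its probe sets, and OAS2 at 3.20 with 32 added on the linear scale. Of 22 IFN gamma effector genes 19 rose, with a median of 2.42. Beside IDO1, PLAAT4 and IL18BP the leading member was TNFSF13B, a B cell survival factor (4.88). Among receptor, STAT and IRF genes 6 of 17 rose, with a median of 0.46 that was 0.18 with the median of each gene's probe sets: the largest rise was that of the transcription factor IRF1 (3.63), followed by IRF9 (1.87), the feedback inhibitor SOCS1 (1.28) and JAK2 (1.27). With the median of the probe sets SOCS1 (4 probe sets) was at 0.16 and JAK2 (3 probe sets) at 0.84. The medians of the guanylate-binding, antiviral, effector and receptor lists were each at percentile 100.

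Other immune lists also rose in part. Among chemokines 5 of 9 rose, with CCL2 (1.82) and CXCL8 (1.19) after the CXCR3 ligands, and the list median was 0.05. Of 16 cell death genes 5 rose, including CASP1 (1.71), the death ligand TNFSF10 (1.68), the necroptosis effector MLKL (1.60) and the DNA sensor AIM2 (1.45), with a median of 0.44 that was 0.26 without the _x_at and _s_at probe sets. AIM2 was at 0.66 with 32 added on the linear scale, and TNFSF10 at 0.99 with the median of its probe sets. Among complement and coagulation regulators 3 of 7 rose: SERPING1 (2.66), C1R (1.97) and C1S (1.61), with a list median of 0.04. Of 16 NF-kB and inflammatory genes 3 rose, CSF1 (1.95), PTGS2 (1.74) and IL6 (1.55), and the list median was 0.00. CSF1 was at 1.25 with the median of its probe sets.

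Genes of the fibroblast state and of general cell functions moved little. Of 36 extracellular matrix genes COL4A1 (1.12) and TNC (1.01) rose, both under 2-fold with the median of their probe sets (0.89 and 0.32), and the list median was 0.01. Of 19 contractile and TGF-beta genes 1 rose, the inhibitor SMAD7 (1.24), with a median of 0.02, and 0 of 17 fibroblast markers passed 2-fold, with a median of 0.00. None of the 36 cell cycle genes passed 2-fold. Their median was -0.38 at percentile 0.0, with 31 of 36 below 0, and it was 0.56 when arrays were centred on the median level of the reference genes, against 0.94 for all genes. The p53 targets had a median of -0.22, which was 0.02 without the _x_at and _s_at probe sets and 0.72 when centred on the median level of the reference genes, and 0 of 9 passed 2-fold. Among stress response genes ATF3 rose by 2.46 (1.42 with the median of its probe sets) and HMOX1, which degrades heme, fell (-1.30), with a median of 0.00. FOS was the 1 immediate early gene that fell (-1.35, and -0.80 with 32 added on the linear scale), and the list median was 0.00. The medians of cholesterol synthesis, oxidative phosphorylation and ribosomal protein genes were -0.03, -0.05 and -0.01, or 0.91, 0.88 and 0.93 when centred on the median level of the reference genes, with no member past 2-fold. The ribosomal median was 0.02 with loess scaling. Among 11 reference genes the transferrin receptor TFRC fell (-1.09, and -0.88 without the _x_at and _s_at probe sets), and the median was 0.00.

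Markers of other cell types stayed within 2-fold with few exceptions. No B cell marker (16 passing) and no plasma cell gene (11 passing) passed 2-fold, with medians of 0.065 (percentile 100) and 0.02 (percentile 91.1). The B cell median was 0.00 with the median of each gene's probe sets and without the _x_at and _s_at probe sets. The B lymphoblastoid list had a median of 0.09 (percentile 99.97, and 0.03 with the median of each gene's probe sets) and 1 raised member, the adhesion gene ICAM1 (2.48), which is also on the effector list. Of 6 T cell markers that passed, IL7R rose (1.06, and 0.94 with the median of its probe sets). No myeloid, epithelial or endothelial marker passed 2-fold, and the medians of these lists and of the T cell markers were 0.00.

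The falls after IFN gamma were fewer and smaller. The largest was that of TNFRSF10D, a decoy receptor for the death ligand TNFSF10, which went from 9.69 to 6.18 (-3.52, 11.4-fold lower). It was followed by CEMIP, which takes part in hyaluronan breakdown (-2.30), CSGALNACT1, an enzyme of chondroitin sulfate synthesis (-2.28), CNIH3 (-2.1), the actin-binding SYNPO2 (-2.07) and RGS4 (-2.0), a regulator of G protein signalling. The remaining members of the 12 were the zinc transporter SLC39A10 (-1.95), KLHL13 (-1.87), the fatty acid binding protein FABP4 (-1.84), SLC35F3 (-1.76), the urea transporter SLC14A1 (-1.73) and FIBIN (-1.72). With the median of their probe sets FABP4 was at -0.92, SLC35F3 at -0.90, CNIH3 at -1.05, CSGALNACT1 at -1.14 and SYNPO2 at -1.16. With 32 added on the linear scale KLHL13 was at -1.24 and SLC14A1 at -1.02. Of the 85 lowered genes 4 were on a list: CALR, FOS, HMOX1 and TFRC.

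Other probe sets of the called genes were read as a check within the arrays. Of 243 raised genes 120 had another probe set that passed the filter, and for 83 of them (69.2%) another was also at least 2-fold higher. Of 85 lowered genes 41 had one, and for 21 (51.2%) another was at least 2-fold lower. None of these genes had another probe set past 2-fold in the opposite direction. In PGF against untreated MRC5 another probe set was past 2-fold in the same direction for 645 of 908 higher and 912 of 1176 lower genes, and in the opposite direction for 3 and 1.

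The second comparison set PGF against untreated MRC5, where cell type, donor and culture differed together. B cell genes stood highest in PGF. The immunoglobulin joining chain JCHAIN was 8.66 higher, the plasma cell receptor TNFRSF17 8.43, the surface antigen MS4A1 (CD20) 8.30, the light chain gene IGLC1 8.19, the survival gene BCL2A1 7.94, LAPTM5 7.87, the lymph node homing receptor CCR7 7.81, the B cell coactivator POU2AF1 7.77 and PLAC8 7.59. The class II genes HLA-DQA1 (8.61), HLA-DRA (7.77) and CD74 (7.6) completed the 12 largest differences upward. HLA-DQA1 was dim in MRC5 (3.66), and its difference was 6.80 with 32 added on the linear scale and 5.72 with the median of its probe sets. POU2AF1 was at 3.95 and CD74 at 4.78 with the median of their probe sets. IGLC1 had 9 probe sets, whose differences ran from -0.04 to 8.19. It was at 0.54 with the median of their levels on each array and at 0.16 without the _x_at and _s_at ones.

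The genes that stood lowest in PGF came in part from the extracellular matrix and contractile lists. LOXL1, MMP1 and COL4A2 were on the former, and CCN2, CALD1 and TPM2 on the latter. None of the genes that stood lowest was on the fibroblast marker list. GREM1, a secreted BMP antagonist, was at 12.68 in MRC5 and 2.88 in PGF, a difference of -9.80 that was -7.39 with 32 added on the linear scale, as the PGF value is near the bottom of the scale. The others were the matricellular CCN2 (-9.10), DKK3 (-8.88), the collagen cross-linking enzyme LOXL1 (-8.83), CALD1 (-8.52), CAV2 (-8.49), TMEM158 (-8.29), the collagenase MMP1 (-8.28), PTX3 (-8.26), the tropomyosin TPM2 (-8.26), EDIL3 (-8.18) and the basement membrane collagen COL4A2 (-8.17). With the median of the probe sets CALD1 was at -1.31, TPM2 at -2.20, DKK3 at -4.38 and EDIL3 at -4.80. Of 13736 genes 1863 were at least 2-fold higher in PGF and 2003 at least 2-fold lower. At 8-fold the counts were 419 and 684. Of the calls 48.2% were higher, a share that was 19.5% when centred on the median level of the reference genes and 33.8% when the median difference of the reference genes was set to 0. These settings moved the median of all genes from 0.02 to -0.69 and -0.29. Of 301 named genes that differed by at least 2-fold in this comparison, 63 and 32 fell short of it under these 2 settings, which shift all genes alike.

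Most members of the B cell, B lymphoblastoid and class II lists were higher. Of 31 B cell markers 27 were higher, with a median of 3.97, and 24 of 25 B lymphoblastoid genes were higher, with a median of 3.93. GPR183 (7.25), SLAMF1 (6.74) and CD48 (6.11, and 3.67 with the median of its probe sets) led the latter after BCL2A1. Of 12 immunoglobulin and plasma cell genes 7 were higher, including IRF4 (6.08, and 4.02 with the median of its probe sets), and the proteoglycan SDC1 was lower (-2.21). The median of this list was 1.70, but 0.39 with the median of each gene's probe sets and 0.17 without the _x_at and _s_at probe sets. The kappa chain gene IGKC was 4.30 higher, but at 0.23 with the median of its 8 probe sets. Of 15 class II genes 13 were higher, with HLA-DPA1 at 7.11, HLA-DQB1 at 6.02 and a median of 4.50 that was 2.0 without the _x_at and _s_at probe sets. HLA-DRB1 (5.55), HLA-DMA (5.40), HLA-DOB (4.50), HLA-DPB1 (4.35), HLA-DMB (4.11), HLA-DRB6 (1.25), CIITA (1.13) and HLA-DRB4 (1.11) were the other members. Some probe sets name several HLA-DRB genes at once, so whether the HLA-DRB4 and HLA-DRB6 values read those genes or related ones was not tested. Without the _x_at and _s_at probe sets HLA-DPB1 was at 0.58, HLA-DOB at 0.00 and HLA-DRB6 at -0.05. The probe sets that then stood for HLA-DPB1 (4.19 in untreated MRC5 and 4.78 in PGF) and HLA-DRB6 (4.56 and 4.51) were under the level filter. That of HLA-DOB read 5.51 on all 3 arrays. These values therefore say little about the differences in PGF. With the median of the probe sets HLA-DRB4 was at 0.14. HLA-DQB2 was at 0.94. HLA-DOA was at 0.00 on the probe set that stands for it and at 5.11 on another. CIITA was at 0.74 with 32 added on the linear scale. Of the class II transcription factors RFX5 (2.60) and RFXAP (1.69) were higher.

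Antigen processing and antiviral genes were also higher in PGF, and class I genes less so. Of 15 antigen processing genes 12 were higher, with a median of 1.74: CTSS by 4.79, ERAP2 by 4.58, PSMB9 by 3.47 and ERAP1 by 3.25. CTSS was at 2.98 without the _x_at and _s_at probe sets and ERAP2 at 2.89 with the median of its probe sets. The 5 probe sets of ERAP1 differed by -0.18, 3.25, 1.46, -0.21 and 0.00, so its direction rests on the probe set. It was at -0.21 without the _x_at and _s_at probe sets. The median of its probe sets gave -0.14, which set different probe sets against each other. CALR was lower (-1.02), and its other probe sets differed by 0.46 and -0.08. The median of its probe sets gave 0.11, which also set different probe sets against each other. In the class I list HLA-F (1.59), HLA-E (1.10) and HLA-B (1.05) were higher and MICA lower (-1.69), with a median of 0.69 that was -0.01 when centred on the median level of the reference genes. HLA-E was at -0.09 and HLA-F at 0.59 without the _x_at and _s_at probe sets, and HLA-B was at 0.90 with loess scaling. Of 38 antiviral genes 28 were higher, among them IFIH1 (6.10), OAS2 (5.74), IFI44L (5.41) and BST2 (5.09), and IFITM3 (-1.69) and IFITM2 (-1.40) were lower, with a median of 1.46. IFIH1 was at 2.92 and OAS2 at 3.64 with the median of their probe sets. IFN gamma effector genes had 12 higher and 3 lower of 22 and a median of 1.05 that was 0.20 without the _x_at and _s_at probe sets, and receptor, STAT and IRF genes 10 higher and 2 lower of 18, with the lymphoid factor IRF8 at 4.66. Guanylate-binding proteins had 1 higher (GBP4, 1.40, and 0.87 with 32 added on the linear scale) and 3 lower members of 4 (GBP3 -5.64, GBP1 -2.39 and GBP2 -1.41).

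The matrix and contractile lists were lower nearly throughout. Of 36 extracellular matrix genes 34 were lower, with a median of -5.48, 15 of 19 contractile and TGF-beta genes were lower, with a median of -5.67 that was -2.90 without the _x_at and _s_at probe sets, and 16 of 17 fibroblast markers were lower, led by the caveolar gene CAV1 (-7.50) and the transcription factor FOXF1 (-6.97). Complement and coagulation regulators had 4 of 7 lower, with C1S at -5.32. In the MHC class III region LTA (4.20), TNF (2.89), LTB (2.76) and AIF1 (1.72) were among 5 higher genes, with LTB at 0.13 without the _x_at and _s_at probe sets, and AGPAT1 (-1.50) and NEU1 (-1.15) were the 2 lower, while the list median of 0.14 was -0.17 with the median difference of the reference genes at 0 and -0.56 when centred on their median level. Of 36 cell cycle genes 10 were higher, with MCM2 at 2.05 and MCM3 at 1.62, and 7 of 15 cholesterol synthesis genes were higher, with HMGCS1 at 2.01. The medians were 0.70 and 0.97, and the cell cycle median was -0.01 when centred on the median level of the reference genes. Among NF-kB genes TNFAIP3 (5.42) and NFKBIA (2.16) led 4 higher members, with NFKBIA at 0.00 without the _x_at and _s_at probe sets, and IL6 (-1.89), LIF (-1.59) and PTGS2 (-1.51) were lower. PTGS2 was at -0.82 with 32 added on the linear scale. Of the T cell, epithelial, myeloid and endothelial markers the higher ones were LCK (5.65), CDH1 (3.89), AIF1 and ESAM (1.12), and the lower ones were IL7R (-2.89), CD4 (-1.47), KRT18 (-4.14) and TEK (-4.16). CD4 was at -0.67 with the median of its probe sets and TEK at -2.44, and with 32 added on the linear scale ESAM was at 0.81 and CDH1 at 2.12. The medians of these 4 lists were 0.00.

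Most of the remaining lists showed single genes more than shifts. The oxidative phosphorylation median lay at percentile 99.4 of the random lists, with 15 of 17 members above 0. Among cell death genes AIM2 (4.54), TNFSF10 (2.42), PYCARD (1.95) and BID (1.54) were among 5 higher of 16, with BID at 0.82 with the median of its probe sets. Of the immediate early genes MYC (1.93), JUNB (1.92) and EGR3 (1.66) were higher and DUSP1 (-3.39) and JUN (-1.99) lower. EGR3 was at 0.74 with 32 added on the linear scale and JUN at -0.70 without the _x_at and _s_at probe sets, and DUSP1 was at -1.59 with the median of its probe sets. Of the stress response genes ASNS (1.81) and ATF3 (1.34) were among 4 higher, and CHAC1 (-3.86) and DNAJB1 (-1.08) were the 2 lower. With the median of the probe sets ASNS was at 0.91 and ATF3 at 0.67, and without the _x_at and _s_at probe sets at 0.00 and 0.67. The p53 targets GDF15 (-3.60), TP53I3 (-1.43) and SESN1 (-1.28) were lower, with GDF15 at 0.33 without the _x_at and _s_at probe sets. CCL5 (3.04) and CCL20 (2.14) were the higher chemokines, and CCL2 (-3.53), CXCL12 (-2.54) and CXCL8 (-2.11) the lower ones, with a median of 0.00. With 32 added on the linear scale CCL20 was at 0.98 and CXCL8 at -1.31, and CXCL12 was at -1.57 with the median of its probe sets. COX7C (1.07) was the 1 higher oxidative phosphorylation gene and GUSB (1.33) the 1 higher reference gene. COX7C was at 0.72 and GUSB at 0.71 with the median of their probe sets, and COX7C was at 0.92 with loess scaling. The medians of the cell death, immediate early, oxidative phosphorylation and reference genes were 0.34, 0.35, 0.60 and 0.31, and -0.36, -0.35, -0.11 and -0.39 when centred on the median level of the reference genes. Those of the stress response, p53, NF-kB, ribosomal and standard proteasome genes were 0.16, 0.15, 0.14, 0.20 and 0.09, and -0.55, -0.56, -0.56, -0.51 and -0.61 when centred so.

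**Figure D3:**
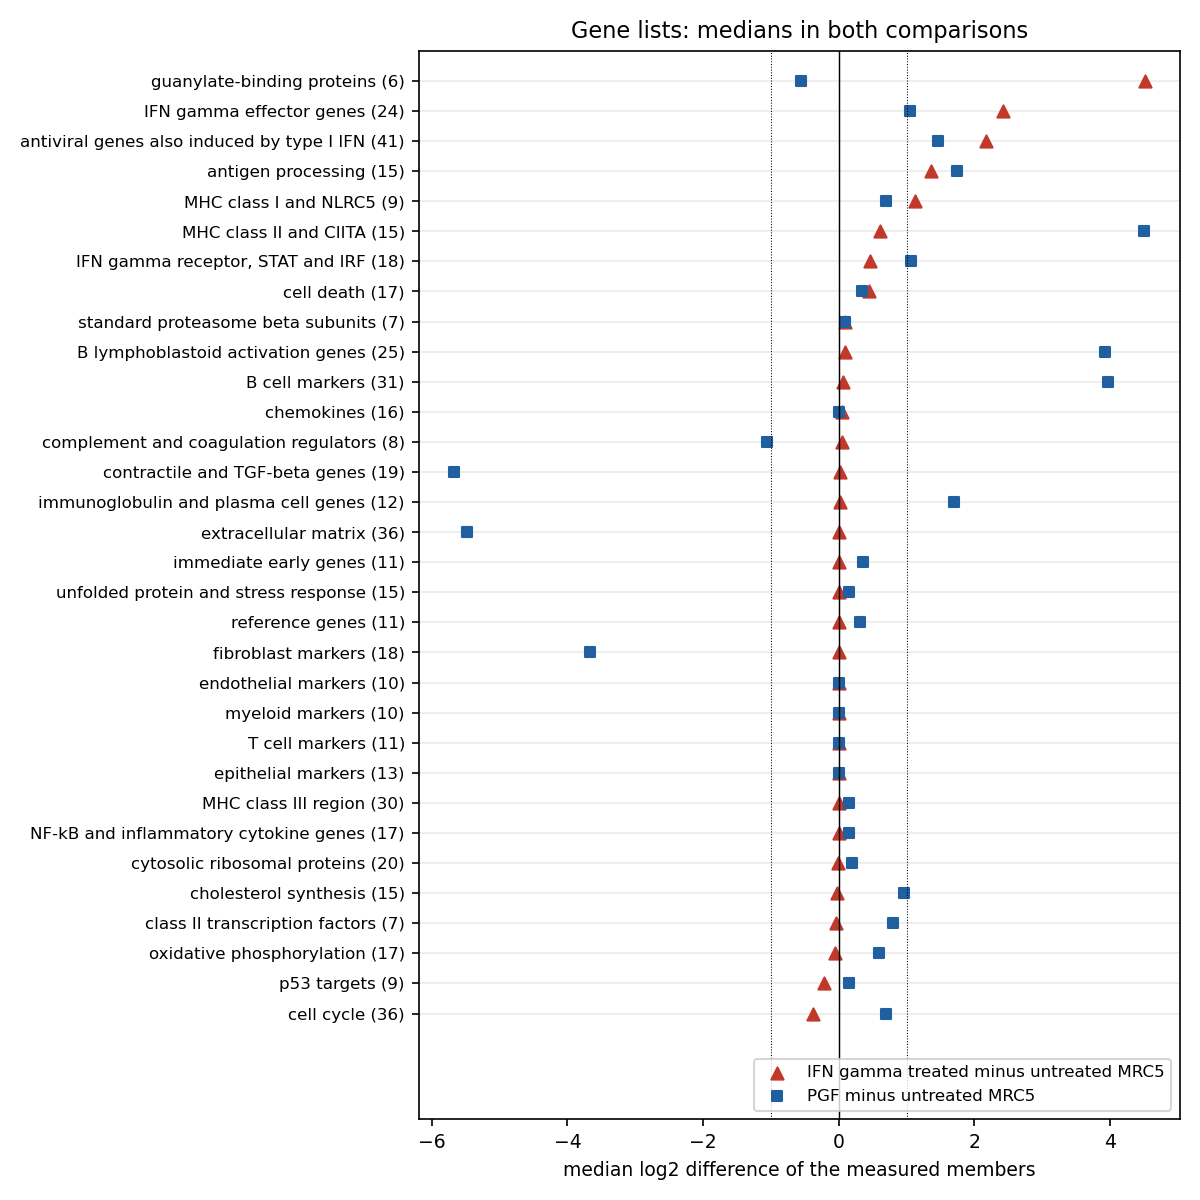
Median log2 difference (x axis) of the measured members of each of the 32 gene lists, with the number measured in parentheses, for IFN gamma treated minus untreated MRC5 (red triangles) and PGF minus untreated MRC5 (blue squares), 1 array per group; dotted lines mark 2-fold. Guanylate-binding proteins stood at 4.52 and -0.55 and MHC class II genes at 0.60 and 4.50.

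The third comparison asked how close IFN gamma brought MRC5 to PGF. Class II genes remained higher in PGF than in treated MRC5 for 10 of 15 members, with a median of 3.26 that was 1.62 without the _x_at and _s_at probe sets: HLA-DQA1 by 8.44, HLA-DQB1 by 5.86, HLA-DRA by 4.84 and HLA-DOB by 4.36. HLA-DOB was at 0.00 without the _x_at and _s_at probe sets, on a probe set that read 5.51 on all 3 arrays. HLA-DQA1 was at 5.56 with the median of its probe sets. CD74 was 3.26 higher. Guanylate-binding, chemokine, effector and antiviral genes were more often lower than higher in PGF, while the receptor, STAT and IRF list had 6 higher and 3 lower of 18 and a median of -0.06. All 5 guanylate-binding protein genes that passed were lower in PGF, with GBP3 at -7.62 and GBP2 at -6.63. Of 10 chemokine genes 6 were lower, led by CXCL11 (-10.06), CXCL10 (-8.59) and CXCL9 (-6.55), and CCL5 (3.10) and CCL20 (2.14, and 0.98 with 32 added on the linear scale) were higher. Of 23 effector genes 14 were lower, with IDO1 at -8.22, and 3 were higher. Of 40 antiviral genes 19 were lower and 6 higher. Antigen processing genes lay closer together, with 3 higher (ERAP2 3.68, LGMN 2.40 and ERAP1 1.47), 2 lower (TAP2 -2.05 and TAP1 -2.01) and 10 of 15 within 2-fold. The direction of ERAP1 rests on the probe set: its 5 probe sets differed by 0.00, 1.47, -0.04, -1.93 and 0.00. It was at -1.93 without the _x_at and _s_at ones and at -0.17 when centred on the median level of the reference genes. The median of its probe sets gave -1.92, which set different probe sets of PGF and treated MRC5 against each other. The median of the antigen processing genes was 0.31, and -1.34 when centred on the median level of the reference genes. In the class I list NLRC5 (-1.89), MICB (-1.75) and MICA (-1.67) were lower and the rest within 2-fold, with a median of -0.21. Without the _x_at and _s_at probe sets the median was -1.70 and HLA-E was at -1.72. Cell cycle genes were higher for 20 of 36 members and cholesterol synthesis genes for 10 of 15. Their medians of 1.05 and 1.22 were -0.59 and -0.42 when centred on the median level of the reference genes. In this comparison that centring moved the median of all genes from 0.01 to -1.64. The medians of these lists and of antigen processing stayed above it. In all, 1926 genes were higher and 2007 lower of 13743.

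Genes that rose after IFN gamma were compared with their standing in PGF. Of the 243 raised genes 103 were at least 2-fold higher in PGF than in untreated MRC5, 44 at least 2-fold lower and 96 neither. Both differences share the untreated MRC5 array. Simulated unchanged arrays shared 0.0 genes on average. Their noise was scaled to the spread between the MRC5 arrays, which is too small to reach 2-fold, so this count does not cover differences between separate cultures. Independent lists of 224 and 1391 among the 13072 genes that passed both filters would share 23.8. The arrays are too few to split the shared control, so part of the excess over either value can come from it. The covariance of the 2 differences over genes was 0.105, against 0.0109 in the simulation, which follows from the size of that noise. Against the treated MRC5 array, 29 of the 243 genes were at least 2-fold higher in PGF, 144 at least 2-fold lower and 70 within 2-fold. Of the 85 genes lowered by IFN gamma 59 were also lower in PGF than in untreated MRC5, where independent lists would share 13.0. Random sets matched on the level of the shared untreated array, drawn after this count was seen, held a median of 15 such genes and at most 28, and the error of that array is still shared.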

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

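The tests of the HLA-DQ pattern and the removal of related neighbours were chosen after the values were seen, and the other tests were set before their values were computed.

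Some signals stood in probe sets that the comparisons did not use. An array control probe set without a gene name was 2.1 higher on the log2 scale on the IFN gamma treated array than on the untreated one, and 3.53 higher in PGF. Another such control was 1.82 higher on the treated array and 1.12 higher in PGF. Other probe sets of these controls were up to 0.93 higher on the treated array and 2.70 higher in PGF, and the ribosomal RNA precursor gene RNA45SN5 was 1.60 and 1.88 higher. A difference in RNA quality or labelling between the arrays stays open. Of 2877 probe sets without a symbol that passed the level filter, 27 were at least 2-fold higher after IFN gamma. Of 1163 passing probe sets with several symbols, 13 were at least 2-fold higher.

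HLA-DQA1 and HLA-DQB1 stayed near their untreated levels in treated MRC5, as did HLA-DPB1 and HLA-DOB, while 6 of 13 passing class II genes rose. Probe sets that do not work on this array type are argued against by PGF, where the largest difference of the 11 probe sets that name HLA-DQA1 or HLA-DQB1 without an HLA-DRB gene was 9.09 and 9 of them were at least 2-fold higher. Probe sequences that match the alleles of PGF but not those of MRC5 remain open, because the largest IFN gamma difference of these 11 was 0.44, which such a mismatch and a low transcript level both predict. Probe sets that name HLA-DQB1 together with HLA-DRB genes differed by 2.67, 2.58 and -0.30, and which of their genes they read is not known. A weaker HLA-DQ response of the fibroblasts is a hypothesis that was not tested.

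Genes raised by IFN gamma were often higher in PGF as well. Error of the shared untreated array in single probe sets is argued against as the whole cause. Of the 50 shared genes with another usable probe set, 28 (56.0%) had one that was 2-fold higher in both comparisons, against 0.659% of 6526 genes, a ratio of 85.0. Mean level alone is argued against too. The 103 shared genes lay at percentile 100 of random sets matched on mean level, whose median was 28 and highest 52. That mean includes the treated and PGF values. Sets matched on the untreated level were not drawn for the raised genes. A low untreated level as a cause of higher values in both comparisons therefore stays open. An error common to all probe sets of a gene, such as a difference in the RNA of the untreated culture, stays open, and a shared interferon program in the B-lymphoblastoid line is a hypothesis without a replicate.

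Genes raised by IFN gamma lay next to each other on the chromosomes. Among the 13105 placed genes, 39 neighbouring pairs were both raised, at percentile 100 of random sets matched on level, whose median was 4 and highest 14. Probe sets that read each other's transcripts in tandem gene families were considered as a cause, through pairs of different names. Of the pairs, 13 had symbols that differ within the first 3 letters, where random sets had a median of 4 and a highest count of 13 (percentile 100). With 2 pairs of related genes, such as CD69 with CLEC2B, left out of the observed count alone, 11 remained, at percentile 99.8. Families can also interleave, as TAP1 and TAP2 do with PSMB8 and PSMB9, and PARP9 and PARP14 with DTX3L. Reading within such families would give pairs of different letters too, so these counts do not decide on that cause. The other 26 pairs remain open to it as well, and shared regulation of neighbours is a hypothesis that these data do not test.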

How the results depend on the processing

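Setting the median difference of the reference genes to 0 was chosen after the data were seen. Centring on the median level of the reference genes moved every count: 3977 genes were then higher and 7 lower after IFN gamma, 854 higher and 3534 lower in PGF, and 329 raised in both. The gene at the median of the 11 reference genes was TFRC at 11.18 in untreated MRC5, HPRT1 at 10.24 in treated MRC5 and YWHAZ at 11.88 in PGF, so this centring shifted each array by the gap between different genes. With the median difference at 0 the counts were 243, 86, 1303, 2556 and 87. Adding 32 on the linear scale, which damps dim values, left 49 lowered genes after IFN gamma. A 1.5-fold threshold gave 477 higher and 403 lower after IFN gamma, 3150 higher and 2759 lower in PGF and 205 raised in both. A 4-fold threshold gave 96, 6, 730, 1105 and 29. Under the other settings the counts stayed within 1.5 times: 186 to 249 raised, 63 to 86 lowered, 1431 to 1910 higher and 1566 to 2081 lower in PGF, and 71 to 104 raised in both. With the median of a gene's probe sets 187 of the 243 raised and 49 of the 85 lowered genes were called again, and without the _x_at and _s_at probe sets 178 and 66. None of the 123 named genes that differed by at least 2-fold after IFN gamma changed sign under a setting that gave it a value. Only 96 of them had a value without the _x_at and _s_at probe sets. The shifts of reference centring are too small to change a sign. In PGF, CALR was at 0.11 and ERAP1 at -0.14 with the median of the probe sets, and without the _x_at and _s_at probe sets ERAP1 was at -0.21, GDF15 at 0.33, HLA-DRB6 at -0.048 and HLA-E at -0.094. Different probe sets then stood for these genes, and with the median those for CALR and ERAP1 also differed between the arrays. The probe set that stood for HLA-DRB6 was under the level filter on both arrays. Why the probe sets disagree was not tested. Centred on the median level of the reference genes, the medians of PGF against treated MRC5 were -0.59 for the cell cycle and -0.42 for cholesterol synthesis, for the same reason as the counts. The median of all genes was then -1.64, so both lists stayed above it. No detection call was used, so differences of dim genes have no measured background, and 1 array per group leaves the variation between cultures unknown.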

Other observations

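The genes in this part were chosen after their values were seen. Of the 243 genes raised by IFN gamma, 138 were on none of the fixed lists. After CMPK2 the largest rises among them were those of the transcription factor BATF2 (4.90), EPSTI1 (4.55) and the lymphocyte activation antigen CD69 (4.40), followed by TMEM140 (3.69), LRATD1 (3.64), CLIC2 (3.62), LRRTM2 (3.33), FAM117B (3.28) and GJD3 (3.20). Several had known links to interferon or antiviral defence, such as the cytidine deaminase APOBEC3G (3.06), the ubiquitin ligase RNF213 (3.01), RTP4 (2.89), PLSCR1 (2.65), PARP12 (2.39) and DTX3L (2.29). CD69, CLIC2 and APOBEC3G were also higher in PGF than in untreated MRC5, by 5.18, 6.38 and 5.0. GJD3 (-0.37) was within 2-fold there, BATF2 and LRRTM2 did not pass the level filter in that comparison, and LRATD1 was lower (-3.83). The protease inhibitor A2M rose by 2.46 after IFN gamma and was 3.27 below untreated MRC5 in PGF.

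The MHC interval, taken as the genes from GABBR1 to KIFC1 in chromosomal order, held 107 genes that passed the filter of treated against untreated MRC5. Of these 15 rose after IFN gamma, a share of 14% against 1.85% of all placed genes, and 0 fell. In PGF 29 of the 107 (27.1%) were at least 2-fold higher, against 10.6% of all placed genes. Both shares keep the filter of the MRC5 arrays, which leaves out genes bright in PGF alone, such as HLA-DQA1. Over all genes that passed the filter of PGF against untreated MRC5 the share was 13.6%, and that of the interval was not computed. The raised genes of the interval included 7 that neighbour each other among passing genes, in the order TAP2, PSMB8, PSMB8-AS1, TAP1, PSMB9, HLA-DMB and HLA-DMA. PSMB8-AS1 lies antisense to PSMB8, rose by 1.63, and whether its probe set also reads PSMB8 was not tested. The pseudogene HLA-J (1.26) rose as well, on an _x_at probe set.

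The cell cycle list did not move as a block after IFN gamma. The 6 MCM genes of the replicative helicase had a median of 0.03 and the 13 members that act in DNA replication or at the G1/S transition one of -0.04, with 8 of 13 below 0. The other 23 members, mostly mitotic genes, had a median of -0.39, and 23 of 23 were below 0. Among them TTK differed by -0.75, PLK1 by -0.72, BUB1 by -0.65 and CCNB1 by -0.60. All lay within 2-fold, and the split of the list was made after the values were seen. In PGF, MCM2 (2.05), MCM3 (1.62), MCM5 (1.44) and MCM6 (1.40) were among the 10 members at least 2-fold above untreated MRC5, and MCM4 (0.79) and MCM7 (0.71) were not.

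The genes raised by IFN gamma but at least 2-fold lower in PGF than in untreated MRC5 numbered 44, and no list was tested among them. As examples, the collagen gene COL4A1 was -6.17, the growth factor VEGFC -5.63 and the complement protease C1S -5.32 in PGF, after rises of 1.12, 1.41 and 1.61. The metallothionein genes MT1E, MT1F and MT1X rose by 1.44, 1.19 and 1.04 after IFN gamma and were at -3.31, -2.12 and -3.80 in PGF. All were read by _x_at probe sets, which can read related transcripts, so whether these are separate rises was not tested.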
